A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

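Spo11 is the protein that makes the DNA double-strand breaks of meiotic recombination, and after each break it stays covalently attached to a short DNA oligonucleotide. Sequencing these oligonucleotides (Spo11 oligos) maps where breaks formed. Per the labels' protocols, cells of the budding yeast strain SK1 carrying Flag-tagged Spo11 were sporulated in potassium acetate, the tagged protein was purified from whole-cell extracts, and the oligos it carried were recovered, tailed, ligated to adaptors and sequenced. Samples were taken at 4 h and 6 h in meiosis, with 2 biological replicates at each time according to the labels. Replicate numbers follow the letters a and b of the labels.

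The deposited values are raw oligo counts at each base pair of the 16 nuclear chromosomes, 12070898 positions in each library, with the strands not separated and 1 library per file, per the file headers and the values. The genome build sacCer2 and R 3.0.1 are named per the submitters' processing notes. The aligner, the oligo length filter, the treatment of oligos that map to several places and the handling of strand are not given in the sources used here. Oligos from repeated sequence, such as subtelomeric gene families and the ribosomal DNA (rDNA) repeats, can therefore have been dropped, placed at random or counted at 1 copy. Mitochondrial and plasmid sequence was not analysed here. All positions below are 1-based sacCer2 positions.

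The library totals were 3051927 and 3038394 oligos for 4 h replicates 1 and 2, and 2030028 and 3534398 oligos for 6 h replicates 1 and 2. Counts were scaled to 1000000 oligos (RPM) of the nuclear total, without the rDNA region of chromosome XII, taken as 450 to 470 kb. Where the rDNA lies is textbook knowledge, and the borders were settled after the counts there had been looked at. A single oligo was worth 0.328, 0.329, 0.493 and 0.283 RPM in the same order of libraries. The values are shares of each library's oligos and carry no information on the number of breaks per cell, so a higher share in some regions comes with a lower share elsewhere. The oligos were counted without molecular identifiers as far as the sources used here tell, so counting intervals cover counting error only.

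Hotspots were called once, on the mean of the 4 scaled libraries, after smoothing with a Hann window of 201 bp. Runs of at least 25 bp above 2.3 times the genome average were kept and then joined where they lay under 200 bp apart. The order of these last steps was settled in coding, before any result was seen. Of 4057 hotspots, 4054 had at least 10 oligos in at least 2 libraries and were tested. Consecutive 20 kb windows from position 1 of each chromosome, with a last window of at least 10 kb kept, were tested in the same way. The test was the quasi-likelihood test of edgeR 4.0.16 on the counts, with the nuclear totals as library sizes, no covariate and Benjamini-Hochberg adjustment, and a hotspot or window was said to have risen or fallen at an adjusted p under 0.05. Log2 changes are 6 h over 4 h throughout. The 16 chromosomes were tested with limma 3.58.1 on log2 RPM per kb.

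Hotspots were grouped into 7 lists by place or strength, fixed before the data were examined except for the rDNA borders given above, on which the rDNA flanks rest. The tests, the alternatives and the rule for naming hotspots were fixed then too. The lists were the short chromosomes I, III and VI, chromosome ends (under 20 kb from an end), end-adjacent regions (20 to 110 kb), pericentromeres (within 10 kb of the centromere), rDNA flanks (within 50 kb of the rDNA), and the strongest and the weakest 10% of hotspots by mean RPM. Centromere positions were textbook values to the nearest kb. Each list was set against all other hotspots with camera of limma, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 7 lists by Benjamini-Hochberg. A circular shift of the hotspot changes along the joined chromosomes, with 10000 shifts, and thinning of all libraries to the smallest total were added after the data had been seen. Permutation tests over the 16 chromosomes used 100000 permutations, except that the 560 choices of 3 chromosomes were enumerated exactly. All tests were two-sided.

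The hotspots named are the 10 with the highest mean RPM, and the 8 with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 20 RPM whose replicates at one time both exceeded both at the other. The 3 windows with the largest rise and the 3 with the largest fall were named likewise. A gene annotation of sacCer2 was not used here, so the planned test of promoters, the gene lists tied to it and the naming of textbook hotspot genes were not run, and no hotspot is assigned to a gene. No GC content could be computed without the genome sequence of that build.

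The hotspot test was tested on simulated counts for the 4054 hotspots, 200 of them changed. It recovered 14% of changes of 1.25-fold, 72% of 1.5-fold and 100% of 2-fold and 3-fold, with 6 calls among unchanged hotspots. The simulated hotspots were independent and had the same spread at both times. In the data the 4 h pair differed more than the 6 h pair, and neighbouring hotspots shared its deviations. The 6 calls therefore do not give the rate of false calls in the data. The hotspot caller found 163 of 163 planted hotspots with 0 false ones. All planted hotspots stood well above the threshold and the background far below it, so hotspots near the threshold were not tested. The chromosome test recovered 100% of simulated shifts of 0.20 log2 with 1.67% false calls. The simulated chromosomes were independent and had the same spread for all chromosomes and both times. Smaller shifts, like most of those called in the data, were not simulated, so these rates do not carry over to the data. The alternatives tried were TMM scaling, DESeq2 1.42.0, limma on log2(RPM + 1), no low-count filter, a hotspot threshold of 4 times the genome average, hotspots called at each time alone, a replicate block, other list borders, 50 kb windows, chromosomes without their outer parts and each library left out in turn. Leaving out a library leaves a lone library at that time, which is then assumed to vary like the pair at the other time. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.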

Results

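Spo11 oligos were mapped genome-wide in wild-type SK1 yeast at 4 h and 6 h in meiosis, with 2 biological replicates at each time. The comparison of the 2 times asks where along the genome the share of meiotic breaks differed as meiosis proceeded. Outside the rDNA, the 4 h libraries held 3051838 and 3038308 oligos and the 6 h libraries 2029894 and 3534238 (replicates 1 and 2). Oligos lay on 5.0% and 5.03% of positions at 4 h and on 4.16% and 5.40% at 6 h. The 4057 hotspots covered 8.90% of the genome, with a median width of 211 bp among the 4054 tested and a median strength of 120 RPM.

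Hotspot strengths were much alike in all libraries, and the times differed by more than the replicates did. Across the 4054 hotspots, which are not independent replicates, log2 RPM correlated at r = 0.986 between the 4 h libraries and at r = 0.993 between the 6 h libraries, and at 0.972 to 0.979 between libraries of different times. The chi-square per degree of freedom over hotspots was 8.20 for the 4 h pair, 1.92 for the 6 h pair and 11.1 to 18.5 between times. Both pairs thus differed by more than sampling noise, and the 4 h pair by more than the 6 h pair. The first principal component, with 65.5% of the variance, separated the times, and the second, with 23.4%, separated the 4 h libraries from each other.

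Short chromosomes carried more oligos per kb than long ones at both times, and the contrast was larger at 6 h. Chromosome I rose from 99.9 ± 0.637 to 116 ± 0.636 RPM per kb (SD, n = 2), a log2 change of 0.22 ± 0.02 (SE). Chromosomes IX, III, VI, VIII and XII rose by 0.18, 0.14, 0.11, 0.09 and 0.09 on the log2 scale. Chromosomes VII, IV, XIII, XVI and II fell by 0.08, 0.08, 0.07, 0.06 and 0.05. The mean density of I, III and VI was 1.34 times that of the other 13 chromosomes at 4 h and 1.5 times at 6 h. The 6 rises and 5 falls passed limma with Benjamini-Hochberg adjustment, with adjusted p from 8.06e-05 for chromosome I to 0.0295 for chromosome XII. The remaining chromosomes V, X, XI, XIV and XV did not pass, with log2 changes of 0.06, 0.00, -0.03, -0.01 and -0.04. The call count moved with every library left out. The falls lost their calls when either 6 h library was left out, where the noisier 4 h pair alone sets the spread. The mean change of I, III and VI exceeded that of the others by 0.158 and 0.155 log2 without 6 h replicates 1 and 2. Without 4 h replicates 1 and 2 the excess was 0.167 and 0.146.

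Density and its change were both related to chromosome length. Over the 16 chromosomes, log2 RPM per kb correlated with log10 length at r = -0.826 at 4 h (permutation p = 0.00027, adjusted 0.00027). Spearman's rho was -0.688 (permutation p = 0.00425, adjusted 0.00425). At 6 h r was -0.947 (permutation p = 1e-05, the smallest the permutations can give, adjusted 3e-05) and rho was -0.921, with the same p values. The log2 change correlated with log10 length at r = -0.846 (permutation p = 3e-05, adjusted 4.5e-05; rho = -0.85, permutation p = 6e-05, adjusted 9e-05). Adjustment was by Benjamini-Hochberg over the 3 relations. Without chromosomes I and VI, the farthest from the median on the log10 length axis, the 3 values of r were -0.711, -0.907 and -0.788. The mean log2 change was 0.16 ± 0.05 (SD, 3 chromosomes) for I, III and VI and 0.00 ± 0.08 (SD, 13 chromosomes) for the others, a difference of 0.16 (exact permutation p = 0.00893 over 560 choices). With the outer 110 kb of each chromosome left out, which leaves little of the shortest ones, the difference was 0.05 (exact permutation p = 0.391) and the relation with length r = -0.482 (permutation p = 0.0554). These permutations treat the chromosomes as independent, although all were measured in the same 4 libraries and their shares sum to a fixed total. The p values therefore measure spread between chromosomes and not between libraries.

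**Figure D1:**
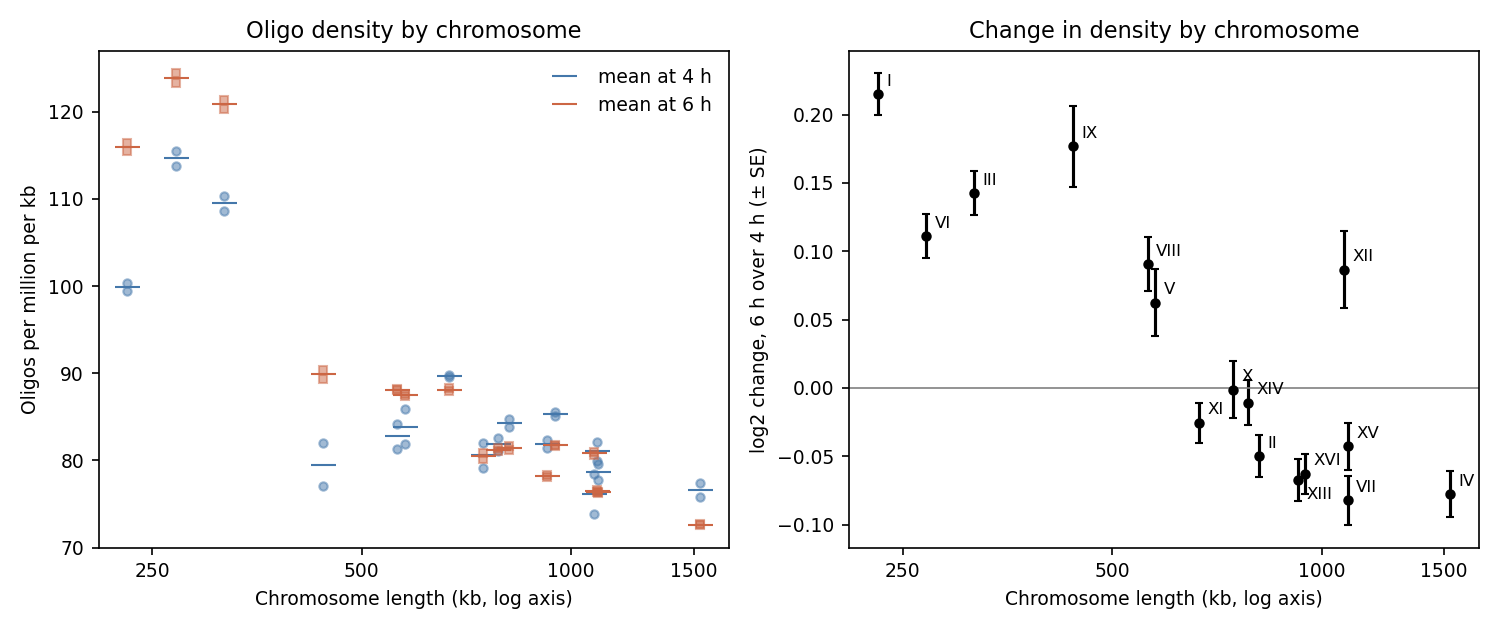
Left, RPM per kb of each chromosome against its length in kb on a log axis, with points for the libraries (blue circles 4 h, red squares 6 h, 2 each) and lines for the means; the vertical axis starts at 70. Right, the log2 change from 4 h to 6 h with its SE, against the same length axis; chromosome I stands highest at 0.22 and chromosome VII lowest at -0.08.

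Chromosome ends gained share from 4 h to 6 h, while the interior held a smaller share at 6 h. Density in the outer 20 kb was low at both times but higher at 6 h, at 15.0 ± 0.779 RPM per kb at 4 h and 18.6 ± 0.333 at 6 h (SD, n = 2). In the end-adjacent regions, 20 to 110 kb from an end, it was 98.3 ± 3.67 at 4 h and 107 ± 0.414 at 6 h, so that their share of all oligos went from 28.3% to 30.9%. Farther than 110 kb from an end, density was 82.9 ± 1.30 at 4 h and 79.6 ± 0.115 at 6 h, and the share went from 70.7% to 67.9%. In all 3 zones both 6 h libraries lay beyond both 4 h libraries on the same side.

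Of the 72 hotspots under 20 kb from an end, 17 rose, 1 fell and 54 did not pass, and 26 rose and 1 fell adjusted over the list alone. Their median log2 change was 0.32, which is 0.39 above that of the other hotspots (camera, Benjamini-Hochberg adjusted p = 1.5e-10; adjusted p = 0.131 with an estimated correlation). The number that rose was 26 and 27 without 4 h replicates 1 and 2, and 4 and 5 without 6 h replicates 1 and 2. Examples were the hotspot at I 372 to 489, which rose from 25.4 ± 1.55 to 59.2 ± 0.762 RPM, and the right end of chromosome IX, whose last 20 kb held a log2 ratio of 0.84. Whether the sequence at I 372 to 489, 0.43 kb from the end, is shared with other ends was not tested. Among 30 chromosome ends with at least 10 oligos in every library, both 6 h libraries exceeded both 4 h libraries at 18 ends and the reverse held at 1, where chance gives 16.7% each way. The mean log2 change per end was 0.29 ± 0.25 (SD, 30 ends; sign-flip permutation p = 1e-05, the smallest the permutations can give). This test treats the ends as independent, although all were measured in the same 4 libraries, and the 4 h libraries alone held 14.5 and 15.6 RPM per kb in the outer 20 kb. The end with the reverse order was the left end of chromosome XI, at -0.27. The times overlapped at the other 11 ends, among them the right end of chromosome XVI, at -0.14.

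Of the 1057 hotspots in end-adjacent regions, 125 rose, 17 fell and 915 did not pass. Adjusted over the list alone, 119 rose and 16 fell. TMM scaling gave 166 rises and 8 falls, and the replicate block gave 187 and 55. The list median was 0.05, or 0.16 above the others (camera, Benjamini-Hochberg adjusted p = 3.4e-07; adjusted p = 0.25 with an estimated correlation). Without 4 h replicate 1 this difference was 0.09, with 194 rises and 136 falls. There were 224 rises and 32 falls without 4 h replicate 2, 38 and 1 without 6 h replicate 1, and 34 and 1 without 6 h replicate 2. By distance, the median log2 change was 0.36 under 10 kb from an end (22 hotspots), 0.26 at 10 to 20 kb, 0.10 at 20 to 40 kb, between 0.02 and 0.07 from 40 to 150 kb, -0.09 at 150 to 200 kb and -0.18 beyond 300 kb (1208 hotspots). The distance bins were chosen after the data had been seen.

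**Figure D2:**
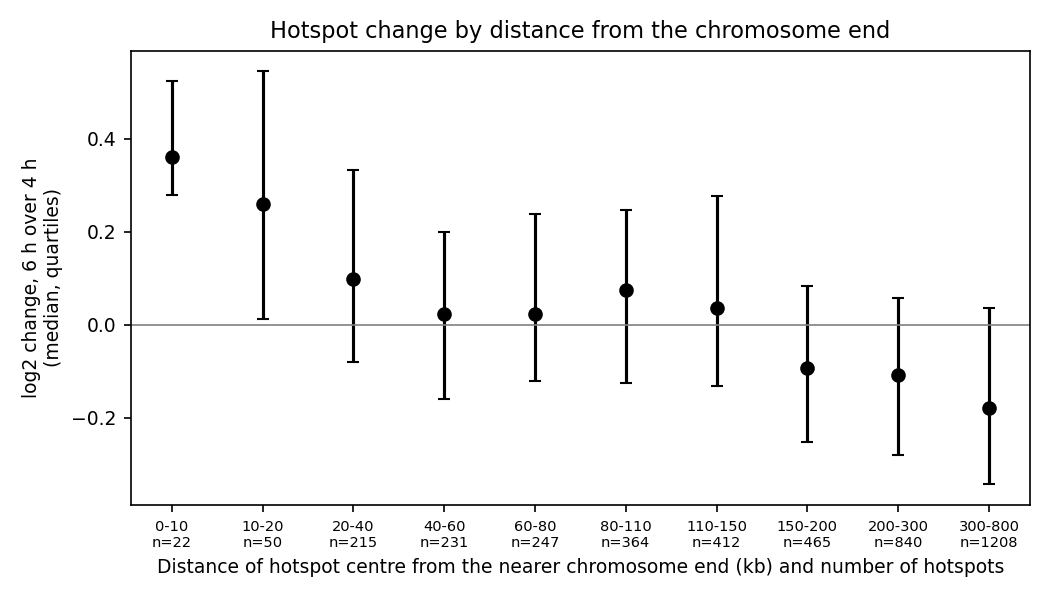
Median log2 change of hotspots from 4 h to 6 h (points; bars span the quartiles) by distance of the hotspot centre from the nearer chromosome end in kb, with the number of hotspots in each bin. The median is 0.36 nearest the end and -0.18 beyond 300 kb.

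The regions beside the rDNA repeats on chromosome XII also held a higher share at 6 h. Within 50 kb of the rDNA, density was 43.8 ± 5.65 RPM per kb at 4 h and 58.4 ± 0.687 at 6 h (SD, n = 2), or 1.34-fold higher. Of the 28 hotspots there, 8 rose and the other 20 did not pass in edgeR, and 12 rose adjusted over the list alone. The hotspot closest to the repeats among those named, XII 448401 to 448598, rose from 37.8 ± 1.74 to 80.9 ± 0.841 RPM. The list median was 0.45, or 0.51 above the other hotspots (camera, Benjamini-Hochberg adjusted p = 1.2e-09; adjusted p = 0.25 with an estimated correlation). The 4 h libraries differed here, at 39.8 and 47.8 RPM per kb, and without 4 h replicate 1 the difference was 0.30, with 9 rises and 1 fall. The number that rose was 20 without 4 h replicate 2, and 6 and 5 without 6 h replicates 1 and 2.

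Pericentromeres, where crossovers are known to be kept low, showed no detectable shift as a group. Density within 10 kb of the centromeres was 55.9 ± 0.779 RPM per kb at 4 h and 56.0 ± 0.227 at 6 h (SD, n = 2). Of the 93 hotspots there, 6 rose, 6 fell and 81 did not pass, and 4 rose and 5 fell adjusted over the list alone. Their median was 0.08 above that of the other hotspots (camera, Benjamini-Hochberg adjusted p = 0.216; adjusted p = 0.473 with an estimated correlation). Taken within 25 kb of the centromere, the difference was -0.03, and over libraries left out it ran from 0.05 without 6 h replicate 2 to 0.11 without 4 h replicate 2. TMM scaling gave 9 rises and 4 falls, leaving out 4 h replicate 1 or 2 gave 14 and 10 or 9 and 13, and 4 hotspots were called without 6 h replicate 1 and 1 without 6 h replicate 2.

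Most hotspots of the short chromosomes did not change detectably. Of 294 hotspots on I, III and VI, 40 rose, 5 fell and 249 did not pass, with the same counts adjusted over the list alone. Their median was 0.07, or 0.14 above the others (camera, Benjamini-Hochberg adjusted p = 5.4e-06; adjusted p = 0.131 with an estimated correlation). The circular shift, which keeps the likeness of neighbouring hotspots, gave a Benjamini-Hochberg adjusted permutation p of 0.109 for this list. There were 67 rises and 20 falls without 4 h replicate 1 and 66 and 10 without 4 h replicate 2, while 13 and 11 rose without 6 h replicates 1 and 2.

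Hotspots that rose and hotspots that fell were both found among the strongest and the weakest. Of the strongest 10% of hotspots (406), 63 rose, 39 fell and 304 did not pass, and 72 rose and 51 fell adjusted over the list alone. TMM scaling gave 79 rises and 24 falls, leaving out 4 h replicate 1 or 2 gave 119 and 96 or 100 and 80, and 13 rose without 6 h replicate 1 and 13 without 6 h replicate 2. Their median was 0.07 above the others (camera, Benjamini-Hochberg adjusted p = 0.0282; adjusted p = 0.25 with an estimated correlation, and 0.0656 without 6 h replicate 2). Of the weakest 10% (405), 11 rose, 4 fell and 390 did not pass, and 0 rose and 0 fell adjusted over the list alone by edgeR, where 32 were higher and 32 lower at an unadjusted p under 0.05. Their median was 0.05 above the others (camera, Benjamini-Hochberg adjusted p = 0.216; adjusted p = 0.341 with an estimated correlation), and 0.02 without 6 h replicate 1 and 0.03 without 4 h replicate 2. The direction depended on the hotspot call, with -0.06 for hotspots called on the 4 h libraries (camera, adjusted p = 0.585) and 0.13 for those called on the 6 h libraries (camera, adjusted p = 0.0175). Without 4 h replicate 1 or 2 there were 25 rises and 14 falls or 12 and 12, and 2 and 4 rose without 6 h replicates 1 and 2.

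Of the 4054 hotspots tested, 280 rose and 319 fell (edgeR, Benjamini-Hochberg), 14.8% in all, and 1329 had an unadjusted p under 0.05. Changes were small, with a median fold of 1.46 among those that rose and 1.41 among those that fell, and 14 rose and 1 fell more than 2-fold. The split depended on the scaling, since TMM gave 379 rises and 208 falls and DESeq2 gave 277 and 124. Both 6 h libraries exceeded both 4 h libraries at 24.0% of hotspots and the reverse held at 36.9%, where chance gives 16.7% each way. The number of calls and their split also depended on single libraries. Without either 6 h library there were far fewer calls, and rises outnumbered falls. Without either 4 h library there were more calls, and falls outnumbered rises.

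The strongest hotspot of the genome, VI 95095 to 96302, rose from 3506 ± 202 to 4810 ± 23.5 RPM (SD, n = 2), a log2 change of 0.46 ± 0.07 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00649). The call was lost without 6 h replicate 1 or 2 (edgeR, adjusted p = 0.0883 and 0.0854). The other 9 of the 10 strongest did not pass. The next strongest, IV 835515 to 836387, held 3364 ± 286 and 3257 ± 55.1 RPM at 4 h and 6 h, VII 609180 to 610473 held 3097 ± 439 and 2938 ± 113.98, and IX 337558 to 339329 held 2796 ± 68.3 and 2686 ± 54.3. The 2 closest to the threshold were IV 550741 to 551708, with a log2 change of -0.26 (edgeR, adjusted p = 0.0537), and VIII 461999 to 462421, with 0.20 (edgeR, adjusted p = 0.0962, and 0.0414 with TMM scaling). Without 4 h replicate 1 or 2, IV 550741 to 551708 passed (edgeR, adjusted p = 0.0213 and 0.00168), as did VIII 461999 to 462421 (0.00386 and 0.0492). Among the 10, II 642455 to 643208 passed without 4 h replicate 1 (edgeR, adjusted p = 0.0123), and VII 609180 to 610473, III 211102 to 212640 and IX 332532 to 333730 without 4 h replicate 2 (0.0132, 0.0281 and 0.0151).

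The hotspots that rose most lay within 110 kb of a chromosome end, except the one beside the rDNA. IX 407913 to 408209 rose from 179 ± 7.30 to 423 ± 13.8 RPM (log2 change 1.24) and X 703508 to 704053 from 203 ± 19.1 to 465 ± 34.4 (1.19), at 31.8 and 42.0 kb from the nearer end. XIV 759295 to 759548 rose from 78.8 ± 1.15 to 174 ± 12.9 RPM (1.14), XIII 91047 to 91424 from 107 ± 28.5 to 239 ± 15.0 (1.15) and IX 388060 to 388246 from 47.6 ± 7.12 to 101 ± 10.0 (1.09). The largest log2 change, 1.28 ± 0.34 (SE), was at the weak hotspot XIII 70303 to 70351, which held 11.3 ± 4.38 and 28.9 ± 12.1 RPM and lost its call without 4 h replicate 2 (edgeR, adjusted p = 0.0856) or 6 h replicate 1 (0.165). The hotspot at I 372 to 489 and the one beside the rDNA rose by 1.22 and 1.10.

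The hotspots that fell most lay farther than 110 kb from an end, with 1 exception. Most tested hotspots lay that far in too. Of the 4054, only 72 lay under 20 kb from an end and 1057 at 20 to 110 kb. Whether the named falls lay there more often than hotspots at large was not tested. XI 403521 to 403716 fell from 276 ± 44.5 to 153 ± 14.3 RPM (log2 change -0.84), and 2 neighbours on chromosome XVI, 543897 to 544081 and 544352 to 544569, fell from 224 ± 0.704 to 127 ± 22.4 RPM (-0.83) and from 128 ± 23.9 to 67.6 ± 1.95 (-0.93). The exception was IV 39013 to 39230, 39.1 kb from an end, which fell from 72.1 ± 20.4 to 36.1 ± 0.929 RPM (-0.99). XII 201535 to 201655, XIII 148766 to 148844, VII 676451 to 676566 and XVI 151974 to 152038 fell by 0.88, 0.88, 0.84 and 0.81 on the log2 scale. These 4 calls were lost without 6 h replicate 1 and without 6 h replicate 2, with edgeR adjusted p from 0.0578 to 0.234, and that of XVI 543897 to 544081 without 6 h replicate 2 (0.0619).

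**Figure D3:**
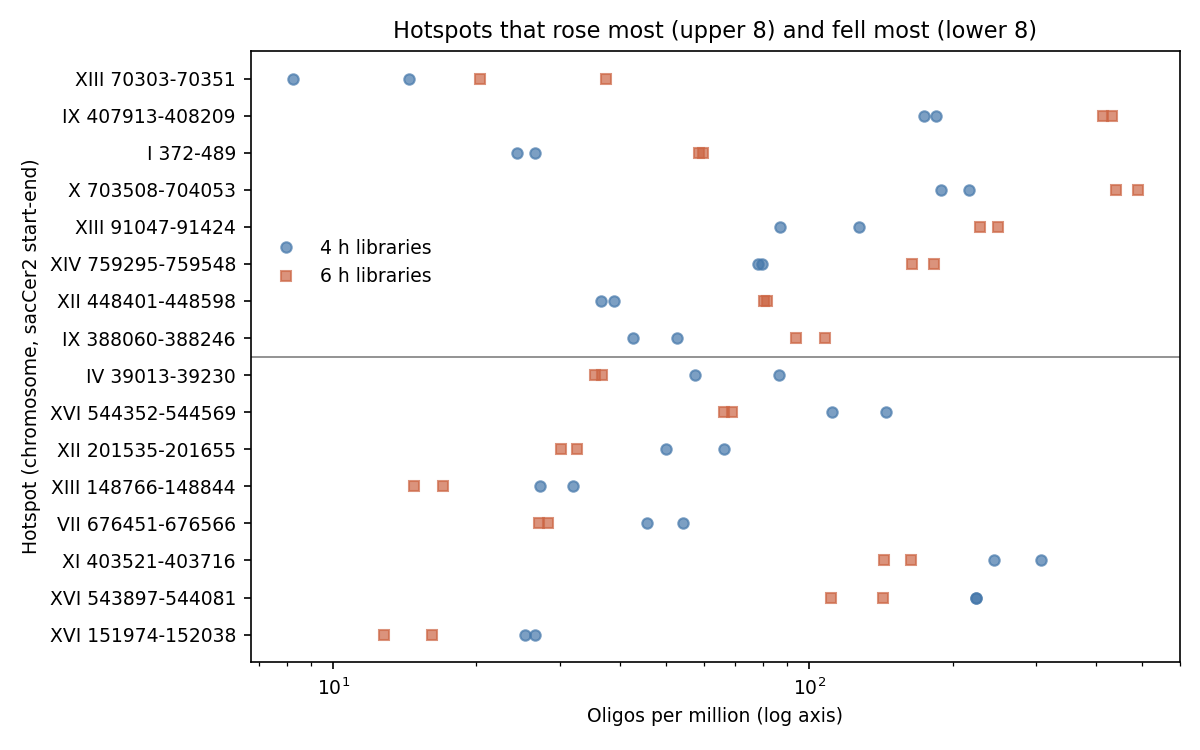
RPM on a log axis in each library (blue circles 4 h, red squares 6 h, 2 each) at the 8 hotspots that rose most and the 8 that fell most, named by chromosome, start and end in sacCer2. Libraries of the 2 times do not overlap at any of them, which the naming rule required.

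In 20 kb windows, which need no hotspot call, 97 of 604 rose and 94 fell (edgeR, Benjamini-Hochberg), and 270 had an unadjusted p under 0.05. Of the 31 windows at an end, 14 rose and the other 17 did not pass, and of 435 farther than 110 kb from an end, 37 rose and 93 fell. The largest rises were at VII 1080001 to 1090947, from 29.1 ± 0.141 to 55.3 ± 0.549 RPM (log2 change 0.93), IX 420001 to 439885, from 194 ± 33.6 to 345 ± 16.3 (0.83), and XII 1060001 to 1078175, from 60.1 ± 4.46 to 105 ± 8.96 (0.81). All 3 were the last window of their chromosome. The one on VII spanned only 10947 bp, with 89 and 88 oligos at 4 h and 113 and 194 at 6 h. Over the full last 20 kb of that end the log2 change was 0.155, and the times overlapped. The largest falls were at IV 740001 to 760000 (-0.54), VII 680001 to 700000 (-0.51) and IV 660001 to 680000 (-0.50). The numbers of windows called were 28 and 29 without 6 h replicates 1 and 2, and 374 and 390 without 4 h replicates 1 and 2.

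**Figure D4:**
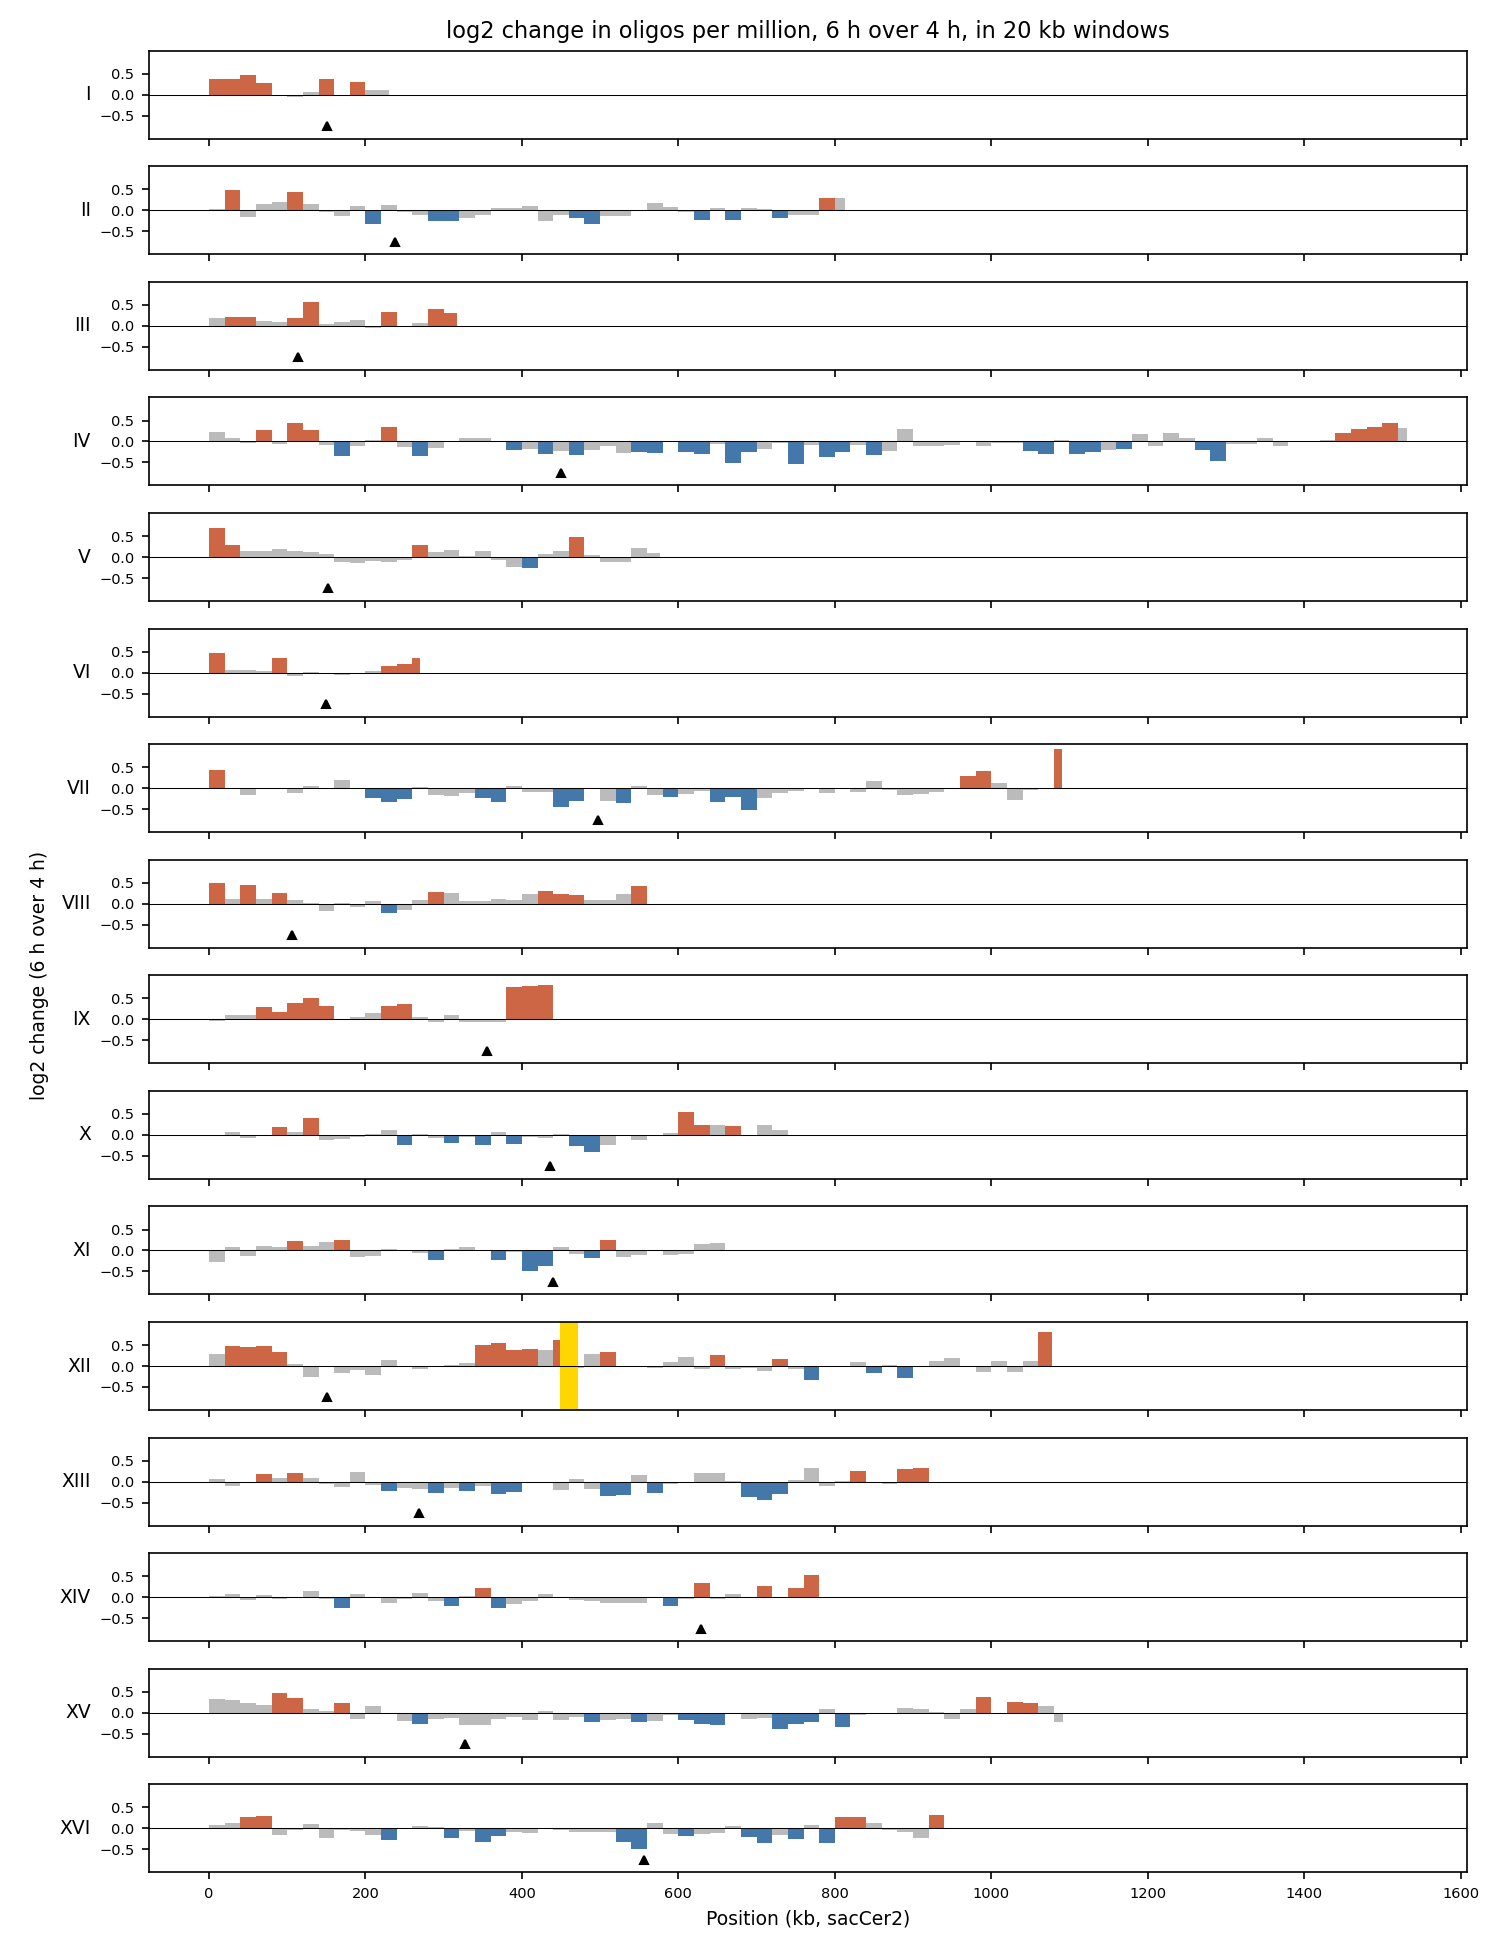
Log2 change from 4 h to 6 h in 20 kb windows along the 16 chromosomes (position in kb, sacCer2), with windows that rose in red, those that fell in blue and the rest in grey; triangles mark centromeres and the yellow bar the rDNA region left out. Of the 97 red windows, 14 lie at an end and 37 farther than 110 kb from one; of the 94 blue windows, 93 lie farther than 110 kb from an end.

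The share of oligos inside hotspots did not detectably differ between the times. It was 89.4% and 89.7% in the 4 h libraries and 88.4% and 89.6% in the 6 h libraries, or 89.6% ± 0.179 and 89.0% ± 0.870 (SD, n = 2). The difference of -0.575 percentage points gave an exact permutation p of 0.667, and 2 libraries against 2 cannot go below 0.333. Without 6 h replicate 1 the difference was 0.04, and without 6 h replicate 2 it was -1.19.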

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

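The test of the 4 h spread beside the rDNA, the intervals for matched distances and the thinning were chosen only after the patterns had been seen, and the patterns themselves had been noticed before any of the tests below.

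The rDNA region of chromosome XII, left out of every comparison, still held oligos above the 3 that a count of 0 allows. There were 89 and 86 oligos in 4 h replicates 1 and 2 and 134 and 160 in 6 h replicates 1 and 2. These are 29.2, 28.3, 66.0 and 45.3 RPM, with exact Poisson 95% intervals, covering counting error only, of 23.4 to 35.9, 22.6 to 35.0, 55.3 to 78.2 and 38.5 to 52.9. Most lay at 459 to 461 kb, the rest at 450 to 452 kb, and the treatment of oligos that map to several repeats, on which these counts depend, is not given in the sources used here.

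The higher share near chromosome ends at 6 h was weighed against depth and background. After all libraries were thinned to the smallest total, the median change of end hotspots was 0.40 (0.398) above that of the others, against 0.39 unthinned. Random thinning leaves the expected share of each hotspot as it was, so it could not have removed the difference. The 6 h libraries were the shallowest and the deepest of all libraries. With only the deeper 6 h library the difference was 0.349 and with only the shallower it was 0.392, so it did not go with depth. More background between hotspots at 6 h would show in weak hotspots. The stronger 36 of the 72 end hotspots lay 0.351 above other strong hotspots. Their median of 138 RPM was close to the median of 120 RPM over all tested hotspots, so they were of middling strength. They were not matched in strength to the hotspots they were compared with, so the comparison cannot decide on background, which stays open. Oligos that map to several subtelomeric copies stay open, since their treatment is not given in the sources used here and was not tested. A change in where breaks form between 4 h and 6 h, the difference the design names, may contribute and stays a hypothesis.

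The higher share of short chromosomes at 6 h could come from nearness to ends alone, because more of a short chromosome lies near an end. Among hotspots 20 to 110 kb from an end, the mean change of I, III and VI exceeded that of the others by 1.55e-05 log2 (exact permutation p = 0.998; 95% interval -0.118 to 0.118). In that zone no excess remained at equal nearness, but the interval leaves room for a length effect of up to 0.118 in either direction.

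The higher share beside the rDNA at 6 h was weighed against misplaced repeat oligos and against the 4 h spread. The 20 hotspots 20 to 50 kb from the rDNA lay 0.486 above other hotspots in median change, which argues against oligos of the repeats placed at its border. Over the flanks, the lower 6 h library exceeded the higher 4 h library by 0.276 log2, but chance gives that order at 16.7% with 2 libraries against 2, so the spread between libraries stays open. The region is 1 locus, and a change in break formation there from 4 h to 6 h may contribute, as a hypothesis.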

How the results depend on the processing

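The circular shift and the thinning were chosen after the data had been seen. Counts of calls moved most with single libraries, from 90 to 1268 hotspots, 28 to 390 windows and 3 to 16 chromosomes, lowest without a 6 h library, where the noisier 4 h pair alone sets the spread. Other scalings, tests, filters and hotspot calls gave 401 to 613 hotspots, and windows of 50 kb gave 79 calls among fewer windows. With the replicate block, the letter entered as a term, 995 hotspots, 240 windows and 12 chromosomes were called, among them IV 550741 to 551708 (edgeR, adjusted p = 0.0299). The labels do not say whether a letter marks a shared culture, and the correlation of the deviations of same-lettered libraries, 0.0968 over 2 pairs, cannot decide it, so pairing stays open and the libraries were treated as unpaired. With an estimated correlation, the median differences of short chromosomes (0.144), ends (0.386), end-adjacent regions (0.157), rDNA flanks (0.512) and the strongest 10% (0.0694) kept their values but not their calls; the circular shift ended the call only for short chromosomes (0.144) and added one for the weakest 10% (0.0519, Benjamini-Hochberg adjusted permutation p = 0.0105). The strongest 10% ranged from 0.0622 to 0.0748 over libraries left out. Pericentromeres taken within 25 kb gave -0.0284, and the weakest 10% gave -0.059 when hotspots were called at 4 h and 0.126 when called at 6 h (camera, adjusted p = 0.0175). Without the outer 110 kb, 6 chromosomes were called, the relation with length was r = -0.482 and short chromosomes exceeded the others by 0.0549. The share in hotspots differed by 0.0403 to -1.19 points over libraries left out. Of the values the alternatives gave for the named hotspots, 271 kept their direction and side of the threshold, called or not, 13 lost a call, 10 gained one and 6, all uncalled, changed sign; some gave none, where DESeq2 set no adjusted p or another hotspot call did not find the hotspot. Those that changed sign were these: IV 835515 to 836387 was 0.0105 with TMM, 0.00913 with DESeq2 and 0.043 to -0.131 over libraries left out, III 211102 to 212640 was 0.0013 with TMM and 0.0701 to -0.173 over libraries left out, and VII 609180 to 610473 was 0.0754 to -0.215, positive without 4 h replicate 1 in each case. Where no construction explains a change, the cause was not tested. The promoter test, its gene lists and the limma pseudocount alternative were not run. The median hotspot count was 344 oligos per library, and thinning to the smallest total gave 575 calls against 599. Whether more depth would add calls was not tested, and the smallest simulated changes were recovered at only 14%.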

Other observations

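The tests of the pericentromeres and of the 4 h libraries, and the runs of windows, were chosen only after the data had been seen.

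Pericentromeres moved in opposite directions on different chromosomes. Moves both ways were not particular to them, since 97 of 604 windows of 20 kb rose and 94 fell. Over all hotspots, both 6 h libraries were higher at 24.0% and both 4 h libraries at 36.9%. Within 10 kb of the centromere, both 6 h libraries exceeded both 4 h libraries on 6 chromosomes and the reverse held on 7, where chance gives 16.7% each way. The log2 change was 0.38 on chromosome I and 0.23 on III, and -0.41 on VII and -0.27 on XV, with a mean of -0.03 ± 0.22 (SD, 16 chromosomes; sign-flip permutation p = 0.582). A candidate explanation is the shift of the whole chromosome: over the 16 chromosomes the change correlated with that of the rest of the chromosome at r = 0.743 (permutation p = 0.00116, Benjamini-Hochberg adjusted 0.00191; rho = 0.729, permutation p = 0.00187; r = 0.661 without chromosomes I and IX). It correlated with log10 length at r = -0.712 (permutation p = 0.00191, adjusted 0.00191 over the 2 relations; rho = -0.726, permutation p = 0.0022; r = -0.676 without the 2 chromosomes farthest from the median on that axis). In size, the change of the whole chromosome was smaller than that near the centromere on I (0.22), III (0.14), VII (-0.08) and XV (-0.04). On VI, IX and XII the change of the whole chromosome was the larger. The signs were opposite on II, V, XII and XIV and the same on the other chromosomes. Near the centromere these changed by 0.10, -0.08, -0.03 and 0.17, and as a whole by -0.05, 0.06, 0.09 and -0.01. The shift of the whole chromosome thus leaves part of the changes near centromeres unaccounted for. Several of the changes near centromeres, on I, III, IV and XVI, had been seen before these relations were tested. The permutations treat the chromosomes as independent, although all were measured in the same 4 libraries.

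Some changes spanned long stretches. Adjacent windows that rose joined into runs of at least 4 windows at IX 60001 to 160000 (log2 ratio of summed shares 0.32) and XII 340001 to 420000 (0.45). Others of that length were XII 20001 to 100000 (0.42), I 1 to 80000 (0.34) and IV 1440001 to 1520000 (0.28). A shorter run, IX 380001 to 439885, had a ratio of 0.79. Windows that fell joined into runs of at most 3, among them XIII 680001 to 740000 (-0.39) and VII 640001 to 700000 (-0.32). Changes of hotspots 2 to 20 kb apart correlated at 0.265, across hotspots, which are not independent. Nearness to ends and chromosome means alone could give this, but with both trends removed the correlation was 0.164. The difference between the 4 h replicates gave 0.175 at the same distances, so these values do not show that neighbours changed together with time.

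The 4 h libraries differed regionally. The difference between them correlated at 0.175 for hotspots 2 to 20 kb apart, against -0.00355 between the 6 h libraries, which argues against counting noise. Over 20 kb windows it correlated with the change from 4 h to 6 h at r = 0.0876 (95% bootstrap interval over chromosomes -0.0563 to 0.201), which argues against replicate 2 being further along the same course as the whole of the difference. In the zones where the times differ, however, replicate 2 lay between replicate 1 and both 6 h libraries. It was 0.265 of the way from replicate 1 to the 6 h mean in the outer 20 kb, 0.45 at 20 to 110 kb from an end, 0.436 beyond 110 kb and 0.431 beside the rDNA, shares that are not independent because they sum to a fixed total. The density ratio of the short chromosomes to the others went the other way, at 1.34 and 1.33 in replicates 1 and 2 against 1.5 in both 6 h libraries. Over all hotspots, replicate 2 lay farther from 6 h than replicate 1 did. Its log2 RPM correlated with 6 h replicates 1 and 2 at r = 0.972 and 0.976, against 0.977 and 0.979 for replicate 1. A further progress of replicate 2 may still contribute part of the difference near ends, beyond 110 kb from an end and at the rDNA, and stays open. The labels give no batch.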
